A study of Mus musculus with 12 samples.

How the data were processed

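Expression was measured in pancreatic tumours of 12 female C57BL/6 mice on 12 one-colour Agilent arrays. Per the labels, the mice carried orthotopic KP tumours and were given vehicle or an inhibitor of focal adhesion kinase (FAKi, 50 mg/kg by gavage) for 14 days. The labels give the age as 8 weeks and name 6 replicates of each group, and total RNA was taken from the tumour tissue. Cy5-labelled cRNA was made from 0.5 µg of RNA. The labels number the tumours but do not state further how they were sampled, so their separateness as animals holds only as far as the labels say.

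The intensity values of each array were made by the authors with Agilent Feature Extraction, per the file headers, which also name the mouse build mm9. Only the red channel was used, and the software had subtracted background and detrended each array by position, per the file headers. A second table of log2 values deposited by the authors covered 38569 probes of the same 12 arrays. Limma is named without a version in the submitters' processing notes, and how those log2 values were normalised is not given in the sources used here. Each column of the table matched its own array best, with r of at least 0.9965 across probes, which are not independent replicates. The column medians lay between 10.71 and 10.90, the values were not centred per gene, and the median absolute difference from a quantile normalisation of the scanner values was 0.15 log2. The filter behind its choice of probes stays unknown.

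Each array held 59305 spots that were not controls, for 56605 probes. Between 71 and 156 spots per array were marked as outliers by the software and left out, and 0 were saturated. The 75th percentile of log2 signal lay between 11.84 and 13.90, and 66.6% to 76.1% of spots were well above background. For arrays, the number of tumours limits the precision.

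The log2 processed signal minus the array's own 75th percentile was averaged over the spots of a probe. A probe was kept if it was well above background on at least 6 of the 12 arrays regardless of group, which left 40460 probes for 27354 genes. Each gene was represented by its probe with the highest mean, taken over the arrays with a value. Other probes of a gene could give a smaller value or the other sign, and their values are given for some genes only. Genes were named through the RefSeq accession of the probe for 32994 probes, through a current symbol for 10224 and through an older synonym for 520. For 12867 probes the array's own name was kept. Probe positions are those of the array's design on mm9.

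FAKi was compared with vehicle by limma (lmFit and eBayes) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The 36 gene lists were fixed before the data were examined and held 586 different genes, of which 558 were measured. A list score was the mean over members of the log2 value minus the gene's mean over the 12 arrays. Scores were compared by an exact two-sided permutation test over all 924 arrangements, adjusted over the 36 lists, with 95% intervals found by inverting that test. The smallest p it allowed was 0.0022. Correlations across tumours used 100000 resamples over 12 or 10 tumours and exact permutation over 6, and the difference of 2 correlations was given intervals from 10000 bootstraps over tumours, of 95% for 1 list and of 99% over 5 lists.

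Named genes followed a rule fixed before the data were examined. It took Ptk2 and Ptk2b, the 10 genes per direction of largest change among those that passed, and, where fewer passed, the genes of smallest unadjusted p. Predicted genes, RIKEN clones and unnamed transcripts were left out of the naming. For each list, 2 members of smallest p are named, and 3 for the p53 targets, but 3 of the genes this rule took are not reported here.

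The arrays lay on 5 slides, identified here by number. Slide 1 held vehicle 3 and 5 with FAKi 5, slide 4 held vehicle 2 and 6 with FAKi 1, slide 2 held vehicle 1 and 4, slide 3 held FAKi 2, 3 and 4, and slide 5 held FAKi 6 alone. Slide was therefore given as a fixed block, within slides 1 and 4, and as a random block.

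Alternatives covered quantile normalisation, normexp background correction with an offset of 50, median centring, the authors' deposited table, other filters on dim probes, the mean of a gene's probes, array weights, a variance trend with robust estimation, a replicate block, and leaving out each array in turn. For lists they covered camera with a preset correlation of 0.01 and with an estimated one, fry, and a median list score. Limma on the list scores, and leaving out vehicle 5, vehicle 6 and FAKi 6 together, were added after the data had been seen.

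The procedure was tested on simulated data for FAKi against vehicle, with 200 changed genes among 27241 in each of 20 simulations built on the real residuals. It recovered 9.48% of genes shifted by 1 log2 unit, 61.5% at 2 and 86.7% at 3, with a mean of 2.5 false calls. Of the unchanged genes, 0.662% to 16.2% had an unadjusted p under 0.05 in a simulation. For lists it recovered 3% of shifts of 0.5 and 36% of shifts of 1. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.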

Results

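Transcript levels were compared between pancreatic tumours of mice given vehicle (n = 6) and of mice given an inhibitor of focal adhesion kinase (FAK) at 50 mg/kg for 14 days (FAKi, n = 6). FAK is a cytoplasmic tyrosine kinase that passes signals from integrins at sites where cells hold on to the matrix. The tumours, which the labels name KP, were grown orthotopically in the pancreas, so each sample was a piece of tissue with tumour cells, stroma and infiltrating leukocytes. The 75th percentile of log2 signal averaged 13.11 ± 0.69 (SD, n = 6) on vehicle arrays and 13.09 ± 0.24 (SD, n = 6) on FAKi arrays. The share of spots well above background was 71.3% ± 3.68 in vehicle and 72.6% ± 2.65 in FAKi tumours (SD, n = 6 each). None of the 4 array measures differed between the groups in the exact permutation test (smallest p = 0.290). Array values differed between all pairs of tumours, with correlations across genes of 0.885 to 0.976.

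The first question was which transcripts differed in tumours after FAK inhibition. Among 27354 genes, 0 rose and 0 fell at an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.345. At an unadjusted p under 0.05 there were 1311 genes, 4.79% of those tested, with 750 higher and 561 lower in FAKi tumours. The groups did not overlap for 65 of 27241 genes with values on all arrays, where chance alone gives 0.216% or 59.0 genes. The median log2 difference over all genes was 0.09, and the median standard error of a gene was 0.33. By other tools or settings, 1 gene passed with normexp background correction, 4 with array weights and 0 with a robust variance trend. Leaving out FAKi 1 gave 3 genes that fell, Rab38 (−2.86), Stac (−3.08) and Zfp422 (−2.32), with Rab38 named after its values were seen. Without vehicle 6 the genes at an unadjusted p under 0.05 numbered 3807, without FAKi 2 they numbered 872 and without FAKi 4 762, and 0 passed in each. With slide as a fixed block 0 genes passed and 489 had an unadjusted p under 0.05.

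Ptk2, which encodes FAK, had nearly the same transcript level in both groups. Its brightest probe, on chromosome 15 at 73046410 to 73046469 (mm9), read 0.58 ± 0.31 log2 in vehicle and 0.65 ± 0.43 in FAKi tumours (SD, n = 6 each). The log2 difference was 0.08 (SE 0.24, limma adjusted p = 0.9995), with 4 of 6 FAKi tumours above the vehicle mean. A further Ptk2 probe gave −0.32, and a dim one, well above background on 5 of 12 arrays, gave −1.70. An inhibitor of kinase activity need not change the transcript of its target, so Ptk2 does not check the labels. Ptk2b, the closely related kinase Pyk2, differed by −0.42 (SE 0.19, adjusted p = 0.9995) and lay below the vehicle mean in 6 of 6 FAKi tumours, while its second probe gave 0.29. The sign for Ptk2 turned with slide as a block (−0.13), with the mean of its probes (−0.12) and without FAKi 3 (−0.0024). Within slides 1 and 4 it was −0.05 and −0.20, and for Ptk2b −0.14 and −0.65.

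No gene passed, so the genes of smallest p are given with that limit. On the higher side these were Gzmf, a granzyme of cytotoxic lymphocytes (2.37, SE 0.49, adjusted p = 0.557), and Igfbp5, a secreted binding protein for insulin-like growth factors (1.12, SE 0.24, adjusted p = 0.580). Pter followed at 1.09, with Apoa1, the main apolipoprotein of high-density lipoprotein, at 1.84, and Tcea2 at 0.99. Mipol1 (1.21), Smoc2, a matricellular protein (1.0003), Syt12 (1.02), Rrp1b (1.14) and Vangl2, a planar cell polarity protein (0.82), completed the 10, with adjusted p up to 0.851. Each of these 10 lay above the vehicle mean in 6 of 6 FAKi tumours. Gzmf and Apoa1 were dim, well above background in 4 of 6 vehicle arrays each. The probes of Rrp1b spanned 0.35 to 1.14, those of Smoc2 0.46 to 1.32 and those of Vangl2 0.44 to 0.82. Some granzyme genes are near copies of Gzmf, so its probe may also read those, which was not checked.

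On the lower side, Btbd11 had the smallest p of the named genes (−2.20, SE 0.36, adjusted p = 0.462), from a probe on chromosome 10 at 85122975 to 85123034 (mm9). Its other probe gave 0.85, so the 2 probes disagreed. Zfp422, a zinc finger gene, differed by −2.03 (SE 0.35, adjusted p = 0.523). It read 0.96 ± 0.34 in vehicle and −1.07 ± 0.83 in FAKi tumours (SD, n = 6 each). Ret, a receptor tyrosine kinase, gave −2.68 and was well above background in 4 of 6 FAKi tumours, and Cfap45, a ciliary protein, gave −2.98 and was above it in 2 of 6. Stac (−2.66), Hpcal4, a calcium sensor of neurons (−2.50), Tns4, a tensin of focal adhesions (−2.24), Osbp2 (−2.07) and Bcas1 (−1.67) followed. The probes of Tns4 spanned −2.24 to −0.10 and those of Osbp2 −2.07 to −0.26. Those of Hpcal4 spanned −2.50 to −0.73 and those of Bcas1 −1.67 to −0.75. Each of these 9 lay below the vehicle mean in 6 of 6 FAKi tumours.

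All 19 genes kept their sign within slide 1, within slide 4 and with slide as a block, and no test was made within a single slide. Slide 1 held FAKi 5 with 2 vehicle tumours and slide 4 held FAKi 1 with 2, so every value within a slide sets 1 FAKi tumour against 2 vehicle tumours, and every block value rests on these 2 FAKi tumours. For Gzmf these values were 1.81, 2.61 and 2.21, and for Zfp422 −2.32, −0.68 and −1.50. Btbd11 gave −2.20, −2.18 and −2.19. Of the 19 genes, 16 had groups that did not overlap, which picking for small p itself favours, so this is no added evidence. Genes picked for small p tend to keep their sign in subsets of the same tumours.

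**Figure D1:**
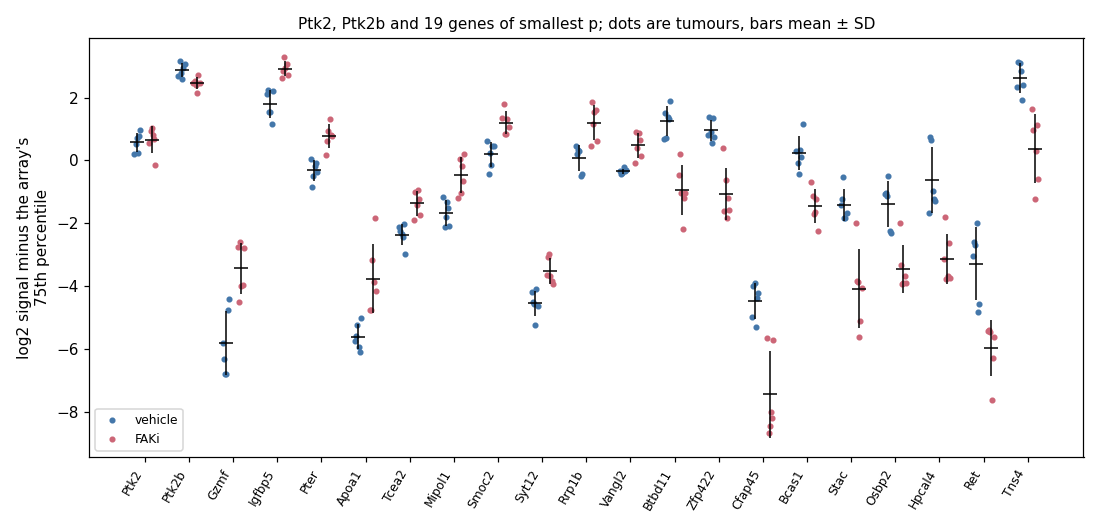
Log2 signal minus the array's 75th percentile (y axis, log2) for Ptk2, Ptk2b and 19 genes of smallest p (x axis), with 1 dot per tumour (blue vehicle, red FAKi, n = 6 each) and bars for mean ± SD. Ptk2 overlaps between the groups (0.58 against 0.65), while Zfp422 averages 0.96 in vehicle and −1.07 in FAKi tumours, and no gene shown passed at an adjusted p of 0.05.

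The next question was whether groups of genes tied to adhesion, stroma and immune cells shifted as a whole. Of 36 lists, 0 passed the exact permutation test after adjustment, 2 had an unadjusted p under 0.05 where chance gives 1.8, and 13 shifts were above 0 and 23 below. Camera with a preset correlation called 11 lists, 2 higher and 9 lower, but camera with an estimated correlation called 0 and fry called 0. No member of any list passed over all genes. Adjusted over the list alone, 3 lists had a member that passed, where chance gives about 1.8. That adjustment was made within each list and not across the 36, so these calls are not evidence of a change by themselves. The shift kept its sign within both slides 1 and 4 for 13 lists, and with slide as a block for 25. Signs turned under quantile normalisation, normexp or median centring for the cytotoxic, STAT3, endocrine, contractile, T cell, ductal and muscle lists. The mean shift and the median member differed in sign for the inflammatory fibroblast, T cell, STAT3, ductal and muscle lists, and camera's direction differed from the mean for STAT3, endocrine pancreas and gut epithelium.

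Acinar pancreas genes, which encode digestive enzymes of the normal gland, shifted by 0.62 log2 towards FAKi tumours (95% 0.12 to 1.08, exact permutation p = 0.0173, adjusted p = 0.545), which did not pass. Of 17 measured members, 16 lay above 0 and 0 passed, adjusted over the list alone or over all genes. The trypsinogens Prss2 (1.23, SE 0.39) and Try4 (1.68, SE 0.79) had the smallest p, and such near-identical copies may share probe targets. The acinar shift was 1.04 within slide 1, −0.04 within slide 4 and 0.50 with slide as a block. Camera called the list higher, with an adjusted p = 0.616 for an estimated correlation.

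Targets of the tumour suppressor p53 shifted by −0.18 (95% −0.33 to −0.03, exact permutation p = 0.0303, adjusted p = 0.545), which did not pass. Of 13 measured members, 3 fell when adjusted over the list alone and 0 over all genes. These were Pmaip1, a mediator of apoptosis (−0.91, SE 0.26), Ccng1, a cyclin (−0.78, SE 0.24), and Phlda3, an inhibitor of Akt (−1.05, SE 0.34), each below the vehicle mean in 6 of 6 FAKi tumours. With slide as a block all 3 calls ended (limma adjusted p = 0.257 over the list), with Pmaip1 at −1.28 in slide 1, −0.58 in slide 4 and −0.93 with the block, Ccng1 at −1.11, −0.51 and −0.81, and Phlda3 at −1.76, −0.15 and −0.96. All 3 also ended without any 1 of vehicle 2, vehicle 5, FAKi 4 or FAKi 5, those of Ccng1 and Phlda3 without FAKi 2, and that of Phlda3 without vehicle 3 or FAKi 6 (adjusted p of 0.0720 to 0.0949). The list shift was −0.10 within slide 1, −0.09 within slide 4 and −0.10 with slide as a block. Camera called the list lower, with an adjusted p = 0.195 for an estimated correlation.

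In the adhesion and matrix groups, 0 of 28 focal adhesion genes passed, adjusted over the list alone or over all genes, and the list shifted by −0.03 (95% −0.30 to 0.24). Pxn, the scaffold paxillin, gave 0.47 (SE 0.28), beside −0.42 for Ptk2b. Of 27 fibrillar collagen and matrix genes, 0 passed and the shift was −0.02 (95% −0.62 to 0.57), with Thbs1 at −0.91 (SE 0.41) and Fmod at −0.65 (SE 0.47). Among 12 contractile myofibroblast genes 0 passed and the shift was −0.02 (95% −0.68 to 0.74), with Cald1 at 0.35 and Synpo2 at −0.83. Slide 1, slide 4 and the slide block gave −0.18, 0.09 and −0.04 for focal adhesion, −0.34, 0.56 and 0.11 for matrix, and −0.46, 0.39 and −0.03 for contractile genes.

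Fibroblast genes had 1 of 18 members that rose when adjusted over the list alone and 0 over all genes. That gene was Smoc2 (1.0003, SE 0.25), while the list shifted by 0.19 (95% −0.58 to 0.98) and Tcf21, well above background in 4 of 6 vehicle and 5 of 6 FAKi tumours, gave 0.47. For Smoc2 slide 1, slide 4 and the block gave 0.98, 1.33 and 1.15, and its call over the list ended with the block (limma adjusted p = 0.392). It also ended without any 1 of vehicle 2, vehicle 4, FAKi 1, FAKi 2 or FAKi 5 (adjusted p of 0.0612 to 0.0695). Of 13 inflammatory fibroblast cytokine genes, 0 passed, adjusted over the list alone or over all genes, with Has2, a hyaluronan synthase, at −2.75 (SE 0.97), Il33 at −1.10 (SE 0.41) and a list shift of −0.18 (95% −0.80 to 0.43). Within slides 1 and 4 fibroblasts gave −0.15 and 0.35 (block 0.10), and inflammatory fibroblasts −0.58 and 0.49 (block −0.05).

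Genes that respond to TGF-beta, a driver of fibrosis, had the largest shift among the signalling lists, −0.42 (95% −0.89 to 0.05, exact permutation p = 0.0714, adjusted p = 0.857). Of 12 members 9 lay below 0 and 0 passed, adjusted over the list alone or over all genes. Ltbp2 gave −0.84 (SE 0.36), but its second probe gave −0.02. Targets of YAP and TEAD, transcription regulators that answer to cell tension, shifted by −0.28 (95% −0.69 to 0.14), and 12 of 16 members lay below 0 with 0 passing on either count. Nt5e gave −1.15 (SE 0.37) and F3, tissue factor, −1.04 (SE 0.37). Camera called both lists lower, with adjusted p = 0.549 and 0.616 for an estimated correlation. Slide 1, slide 4 and the block gave −0.53, 0.15 and −0.19 for TGF-beta and −0.64, 0.09 and −0.28 for YAP and TEAD.

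Among lymphocyte groups, 0 of 19 T cell genes and 0 of 18 cytotoxic lymphocyte genes passed, adjusted over the list alone or over all genes. The shifts were −0.0033 (95% −0.73 to 0.75) and 0.05 (95% −0.88 to 0.9996). Tcf7, a factor of naive and memory-like T cells, gave −0.62 (SE 0.28) and Bcl11b 0.44. Among cytotoxic genes Gzmb gave 1.35 (SE 0.57) and lay above the vehicle mean in 6 of 6 FAKi tumours, while Gzmk gave −1.67 (SE 0.86) and was well above background in 4 of 6 FAKi tumours. Of 16 genes of regulatory T cells and checkpoints 0 passed, the shift was 0.11 (95% −0.51 to 0.76), and Ikzf2 gave −0.66 against 0.45 for Ctla4. The spread of cytotoxic scores was 0.43 in vehicle and 0.90 in FAKi tumours (SD, n = 6 each). Within slide 1, within slide 4 and with the block the values were 1.14, −0.07 and 0.54 for T cells, 1.27, 0.14 and 0.70 for cytotoxic genes, and 1.18, 0.13 and 0.66 for regulatory T cells.

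Myeloid groups also gave 0 passing members, adjusted over the list alone or over all genes. The shift was −0.14 (95% −0.69 to 0.40) over 20 macrophage genes, with the scavenger receptor gene Cd163 at −0.94 (0.003 for its second probe). It was −0.07 (95% −0.50 to 0.34) over 14 genes of monocytes and their recruitment, with the growth factor Csf2 at 1.15 (SE 0.42) and Cx3cr1 at −0.71. Over 19 neutrophil genes it was 0.17 (95% −0.56 to 0.90), with Camp at 0.998 (SE 0.44) and Lcn2 at 0.77. Over 13 dendritic cell genes it was −0.25 (95% −0.78 to 0.28), with Itgae at −1.01 (SE 0.37) and Clec10a at −1.12 (SE 0.53), and camera called it lower with an adjusted p = 0.628 for an estimated correlation. Values for slide 1, slide 4 and the block were −0.10, −0.11 and −0.10 for macrophages, 0.07, 0.46 and 0.26 for monocytes, 1.44, −0.29 and 0.57 for neutrophils, and 0.31, −0.18 and 0.07 for dendritic cells.

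Antigen presentation and interferon genes gave 0 passing members on either count, adjusted over the list alone or over all genes. MHC class II genes shifted by −0.07 (95% −0.63 to 0.53, 11 measured), with H2-Oa at −0.69 and H2-Ob at −0.31 (probes −0.50 to 0.93). MHC class I genes shifted by 0.10 (95% −0.48 to 0.71, 12 measured), with the peptide transporter gene Tap1 at 0.48 and Psmb10 at 0.30. Type I interferon genes shifted by −0.20 (95% −0.84 to 0.41, 20 measured), with Mx1 at −0.72 and Ifit1 at −0.69, and camera called them lower with an adjusted p = 0.911 for an estimated correlation. Interferon-gamma genes shifted by 0.11 (95% −0.87 to 1.05, 15 measured), with the chemokine Cxcl10 at 0.71 and Ido1 at −1.40. In the same order, slide 1, slide 4 and the block gave 0.74, 0.11 and 0.43 for class II, 0.82, 0.46 and 0.64 for class I, 0.51, 0.26 and 0.39 for type I interferon, and 1.28, 0.77 and 1.02 for interferon-gamma.

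Lists of tumour cell state had 1 member that passed within its list. Of 14 STAT3 response genes, Myc, a transcription factor of growth, rose when adjusted over the list alone (1.16, SE 0.30), 0 passed over all genes, and Cebpb gave 0.33. Myc gave 1.76 within slide 1, 0.029 within slide 4 and 0.90 with slide as a block, where its call over the list ended (limma adjusted p = 0.565). That call also ended without any 1 of vehicle 1, 2, 3 or 5 or FAKi 3, 4, 5 or 6 (adjusted p of 0.0524 to 0.0780). The list shift was 0.02 (95% −0.26 to 0.30). Of 23 cell cycle genes 21 lay above 0 and 0 passed on either count, with Ccne1 at 0.74 (SE 0.28) and Aurkb at 0.68 (SE 0.29), a shift of 0.23 (95% −0.20 to 0.63) and a call by camera with an adjusted p = 0.911 for an estimated correlation. Ductal genes shifted by −0.04 (95% −0.84 to 0.81, 22 measured), with Tff2 at 1.39 (SE 0.64) and Cldn3 at −2.46 (SE 1.08), which was well above background in 5 of 6 vehicle and 1 of 6 FAKi tumours, so its size is uncertain. Mesenchymal transition genes shifted by −0.08 (95% −0.72 to 0.55, 16 measured), with Cdh11 at 0.66 and Foxc2 at −1.62. MAPK output genes shifted by −0.03 (95% −0.29 to 0.23, 13 measured), with Ccnd1 at −0.33 and Etv5 at −0.52. In these 3 lists 0 passed, adjusted over the list alone or over all genes. Taken by slide 1, slide 4 and the block, shifts were 0.18, 0.18 and 0.18 for STAT3, −0.08, 0.07 and −0.0044 for cell cycle, 0.68, −0.23 and 0.23 for ductal, −0.65, 0.77 and 0.06 for mesenchymal, and −0.26, 0.02 and −0.12 for MAPK genes.

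Stress groups had 0 passing members, adjusted over the list alone or over all genes. Hypoxia and glycolysis genes shifted by −0.23 (95% −0.62 to 0.15, 18 measured), with Ero1a at −0.93 (SE 0.35) and Pfkp at −0.58 (probes −0.58 to 0.35). Heat shock and unfolded protein response genes shifted by −0.25 (95% −0.56 to 0.06, 15 measured), with Hspa1a at −1.24 and its near-identical copy Hspa1b at −0.82. Camera called both lower, with adjusted p = 0.616 for an estimated correlation in each. Immediate early genes, which answer to handling of tissue, shifted by 0.11 (95% −0.25 to 0.48, 17 measured), with Klf4 at 0.67 and Nr4a2 at 0.64. By slide 1, by slide 4 and by the block, the shifts were −0.35, −0.83 and −0.59 for hypoxia, −0.49, −0.06 and −0.27 for heat shock, and 0.04, 0.21 and 0.12 for immediate early genes.

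Markers of other cells that a tumour piece could hold gave 0 passing members, adjusted over the list alone or over all genes. Endothelial genes shifted by −0.36 (95% −0.98 to 0.31), with 14 of 16 below 0, Vwf at −1.06 (SE 0.35, probes −1.06 to −0.07) and Cdh5 at −1.05 (SE 0.37). Adipocyte genes shifted by −0.82 (95% −2.58 to 0.90), with 12 of 13 below 0 and Adipoq ranging widely (SD 3.64 in vehicle and 3.99 in FAKi tumours, n = 6 each). Camera called both lower, with adjusted p = 0.616 for endothelium and 0.708 for adipocytes with an estimated correlation. For slide 1, slide 4 and the block they were −0.56, 0.03 and −0.26 for endothelium and −1.19, 0.30 and −0.44 for adipocytes. B and plasma cell genes shifted by −0.31 (12 measured, block −0.17), with Derl3 at −0.997 and Blk at −1.65, and erythroid genes by −0.33 (9 measured, block −0.33), with Hbb-bt at −0.99. Mesothelial genes shifted by 0.44 (6 measured, block 0.51), with Upk3b at 1.69, and gut epithelial genes by 0.06 (12 measured, block −0.14), with Muc2 at −1.44. Endocrine genes shifted by 0.05 (10 measured, block −0.20), with Chga at −1.50 and Pcsk1 at 1.19. Of these markers, some were not well above background throughout, so their sizes are uncertain, namely Pcsk1 (2 of 6 vehicle tumours), Upk3b (3 of 6 vehicle and 5 of 6 FAKi tumours), Muc2 (5 of 6 and 3 of 6), Adipoq (3 of 6 FAKi tumours) and Blk (5 of 6 FAKi tumours). Skeletal muscle genes shifted by −0.02 (95% −2.70 to 2.76, 13 measured, block −0.67), with Tnni2 at 0.57. Slides 1 and 4 gave 0.65 and −0.99 for B cells, −0.14 and −0.53 for erythroid, 0.15 and 0.86 for mesothelial, 0.78 and −1.06 for gut, 0.40 and −0.80 for endocrine, and −0.50 and −0.84 for muscle genes.

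**Figure D2:**
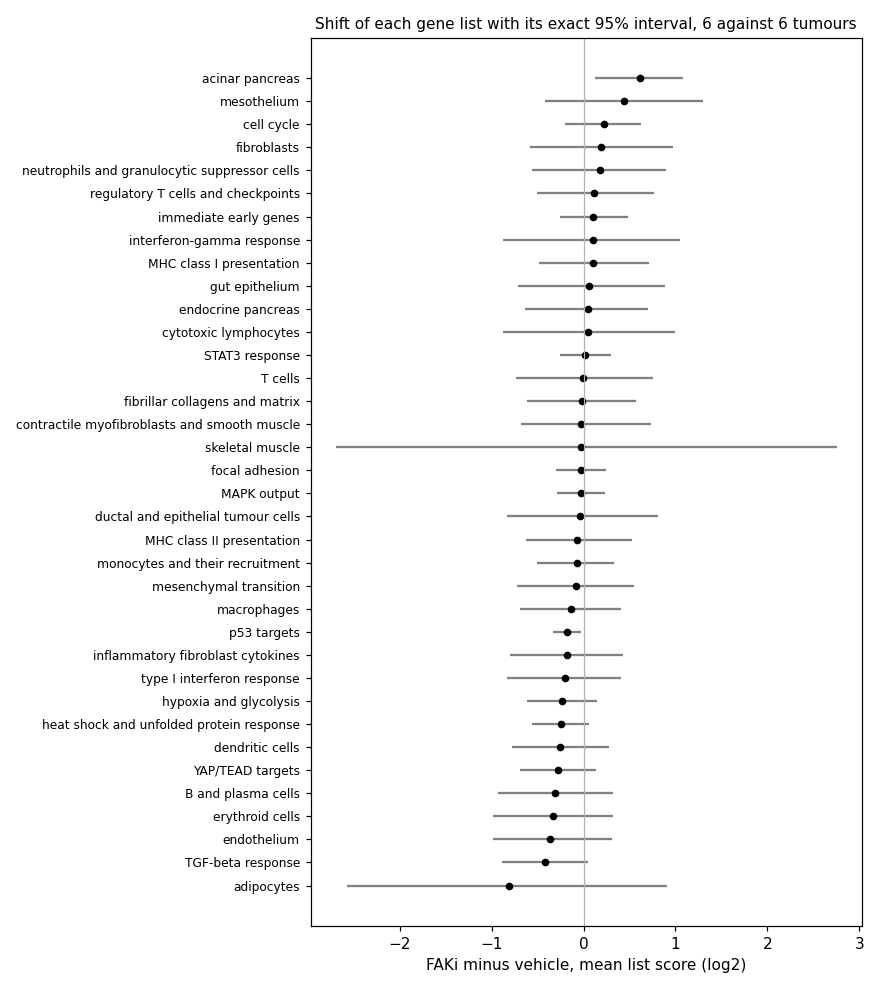
Shift of each of the 36 gene lists (y axis) as FAKi minus vehicle mean list score (x axis, log2), with lines for the exact 95% interval over 6 against 6 tumours. The intervals of the acinar pancreas (0.12 to 1.08) and p53 target lists (−0.33 to −0.03) leave out 0, and 0 lists passed after adjustment over the 36.

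The last question was whether tumours rich in matrix transcripts held fewer cytotoxic lymphocyte transcripts. Over the 12 tumours no relation of the 2 scores was found, with r = −0.07 (permutation p = 0.826) and rho = 0.04 (permutation p = 0.904). So few tumours cannot exclude one. Within vehicle tumours r was −0.03 (exact permutation p = 0.957, n = 6) and within FAKi tumours −0.09 (exact permutation p = 0.839, n = 6). Without the 2 tumours farthest from the median matrix score r was 0.01 over 10 tumours. With slide means taken away it was −0.23, and with group means taken away −0.07. No slide held 6 tumours, so the relation was not computed within one. It was the only relation fixed before the data were examined, so its adjusted p is its own in that family. Counted among 7 relations of list scores, of which the others were chosen after the data had been seen, the adjusted values were 0.826 and 0.904. The sign turned with normexp (0.07) and median centring (0.12), and r without each tumour in turn ran from −0.21 to 0.16.

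**Figure D3:**
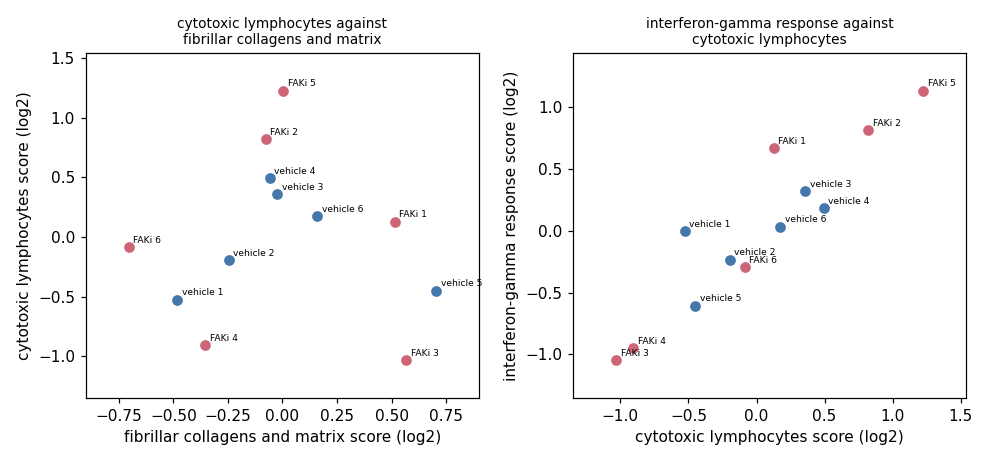
List scores of the 12 tumours (blue vehicle, red FAKi, 1 dot each, log2), with cytotoxic lymphocytes (y axis) against fibrillar collagens and matrix (x axis) on the left and interferon-gamma response (y axis) against cytotoxic lymphocytes (x axis) on the right. No relation was found between the left scores (r = −0.07), while the right ones rise together (r = 0.92).

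Vehicle 6 and FAKi 6 stood apart from the other 10 tumours on the first principal component. Vehicle 5 stood apart on the second, at −154.2 against −23.9 to 51.3 in all other tumours. Its median correlation with the other arrays was 0.930, below the 0.938 of FAKi 6 but above the 0.920 of vehicle 6, the lowest. The first principal component held 30.7% of the variance, did not part the groups (exact permutation p = 0.855) and ran with the array's 75th percentile (r = −0.88 over 12 arrays). The third component, 13.3% of the variance, differed between the groups (exact permutation p = 0.0281), and the second did not (p = 0.569 in the same exact permutation test), with no adjustment over the 3. On the third, FAKi 2, 3, 4 and 5 scored 40.2 to 67.5. FAKi 1 (−34.2) and FAKi 6 (−22.5) lay within the vehicle range of −59.9 to −4.78. FAKi 2, 3 and 4 shared slide 3, which held no vehicle tumour, so group and slide cannot be told apart for them. Limma's array weights were lowest for vehicle 6 (0.198), vehicle 5 (0.352) and FAKi 6 (0.417). With these 3 left out together, an alternative chosen after the data had been seen, 0 genes and 0 lists passed. The smallest adjusted p in limma was then 0.0679, and 4858 of 27354 genes had an unadjusted p under 0.05, against 1311 with all arrays.

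**Figure D4:**
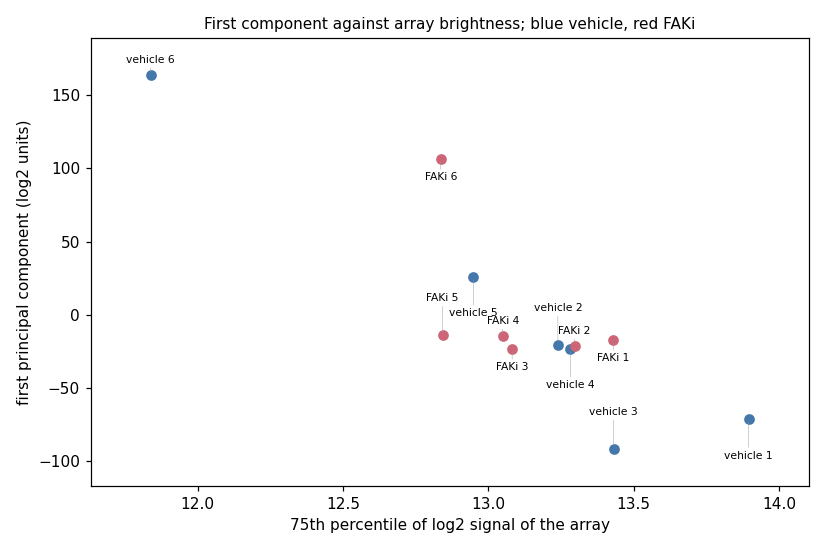
First principal component (y axis, log2 units) against the 75th percentile of log2 signal of the array (x axis) for the 12 tumours (blue vehicle, red FAKi). Vehicle 6 is the dimmest array at 11.84, and FAKi 6 lies far above arrays of like brightness.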

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

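The tests of the segment around Myc and of the arrays that stand apart were chosen only after the result was seen. A tumour was marked for a closer look where its gap to the nearest of its group, over the group's range, passed Dixon's 95% value for 6 samples. Chance marks about 1 in 20 groups, which is 13.4 of the 268 groups tested here, and 11 were marked.

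For named genes, 9 of 186 groups were marked where chance gives 9.3. Among FAKi tumours, Osbp2 read −1.97 in FAKi 1 against −3.93 to −3.32 in the others, and Cldn3 read −2.77 in FAKi 1 against −8.61 to −6.69. In FAKi 3, Synpo2 read 0.064 against −5.29 to −3.50 and Tnni2 read 5.17 against 1.85 to 2.64. Derl3 read −1.92 in FAKi 5 against −3.06 to −2.71, and Camp read −0.25 in FAKi 4 against −3.01 to −2.48. Among vehicle tumours, Pxn read 0.21 in vehicle 6 against 1.01 to 1.25. In vehicle 3, Aurkb read 0.27 against −0.68 to −0.35 and Muc2 read −7.50 against −4.86 to −3.69. None of the 72 groups of list scores was marked, where chance gives 3.6.

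Myc and 7 neighbouring genes on chromosome 15 (60.7 to 62.1 Mb, mm9) were followed up after Myc, Lratd2 (1.46) and Pvt1 (2.35) were seen to be high in the same tumours, while Macroh2a3 among the 8 gave 0.10. FAKi 1 was marked with a score over these 8 genes of −0.85 against 0.59 to 1.33 in the other FAKi tumours, the 1 FAKi tumour inside the vehicle range, and the groups differed by 1.34 (exact permutation p = 0.0108, unadjusted and on genes picked after those values were seen, so treatment stays open). A gain of the segment in tumour cells was a candidate explanation, but the 8 genes varied together within groups at percentile 87.6 of windows of as many neighbours, short of the 95 set for it. The test was then repeated once on the 5 genes that varied together most, with the same picking in every window. Percentile 92.7 fell short again, so neither version bore out a gain. Both versions took group means away, which also removes what a gain held mostly by FAKi tumours would add. They therefore cannot exclude a gain, which stays open. With slide means taken away the percentiles were 96.2 for 8 genes and 99.0 for 5, and with array brightness taken away 88.0 and 95.1, but a segment picked because its genes were high in the same tumours can pass 95 for that reason alone, so slide and brightness stay open.

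FAKi 6 had a median correlation of 0.938 with the other arrays against 0.953 to 0.961 in its group, and lay apart with vehicle 6 on the first principal component. Dim arrays were a candidate explanation, since the component ran with the 75th percentile over the other 10 arrays too (r = −0.72). FAKi 6 lay 3.70 prediction SD from that line and vehicle 6 lay at 1.81. Both were picked for lying apart on this component and left out of the line. A large distance can follow from that alone, so the line does not decide for either. FAKi 6 scored 106.4 on the component at a 75th percentile of 12.84. FAKi 5 at 12.84 scored −13.8 and vehicle 5 at 12.95 scored 26.0. The 75th percentile alone therefore did not set the place of FAKi 6, which rests on FAKi 6 alone. For vehicle 6, the dimmest array, brightness stays open. A first version in residual SD had put FAKi 6 and vehicle 6 at 4.24 and 3.41. It left out the error of a line carried to 11.84, below the 12.84 to 13.90 of the other 10. Normal acinar tissue could not be told apart from other sources, since the median acinar gene lay at percentile 77.3 of level-matched lists in vehicle 6 and 97.5 in FAKi 6, and no other biological explanation was tested.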

How the results depend on the processing

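The array weights, the robust trend and the settings below were fixed before the data were examined. Leaving out vehicle 5, vehicle 6 and FAKi 6 together and limma on list scores were chosen after the result was seen, as were the split tests of array weights and of called genes. No gene or list passed in the primary analysis, and the count of genes stayed at 0 under all settings but normexp (1 gene, a transcript known only by an accession), array weights (4 genes) and the removal of FAKi 1 (3 genes), so that leaving out each array in turn gave 0 to 3. With array weights Osbp2 (−2.46) and Ret (−3.40) fell, as did that same unnamed transcript, and a RIKEN clone rose. The genes at an unadjusted p under 0.05 were 1311, against 5243 with array weights, 3807 without vehicle 6, 872 without FAKi 2, 762 without FAKi 4, 489 with slide as a block and 255 on the slides that hold both groups. No list passed under any setting but camera with its preset correlation (11 lists), and there its calls ended with an estimated correlation. For camera and fry the value of a list is the mean moderated t of its members, for camera minus that of all other genes.

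Other splits of the 12 tumours into 6 and 6 were drawn, 100 of 462 with the real one, over 27241 genes. No split can call fewer genes than the real 0, so the share of 100 of 100 that gave as many decides nothing. Of the 100, 3 called any, and the highest other called 140. That split set all of slides 1 and 3 against slides 2, 4 and 5, but it also held FAKi 2, 3, 4 and 5 on the same side. It was picked as the highest, and the cause of its calls was not tested. In the real comparison the consensus correlation within slides was 0.03, and 0 genes passed with slide as a block and without it. For genes at an unadjusted p under 0.05, 48 of 100 splits gave as many as the real 1308 (highest other 4585), so chance was not excluded. With array weights 5 of 100 gave as many such genes as the real 5233 (highest other 6244) and 7 of 100 as many calls as the real 4 (highest other 514), and chance was not excluded. Camera's 11 lists were reached in 56 of 100 (highest other 26). Without vehicle 5, vehicle 6 and FAKi 6, 1 of 100 splits drawn from 126, the real one, gave 4850 genes (highest other 3578), but those 3 had been picked with the real grouping. With the 3 arrays picked anew in every split, a version added after that one had been seen, 2 of 100 reached 4850, both with the real parting of the other 9 tumours, and the highest with another parting was 4787. That margin was narrow, and the arrays of the version before it had been picked with the real grouping. Of the other 5 of the 7 tests, that of called genes decides nothing, since every split reaches a real count of 0. The rest gave shares of 5 of 100 or more, so chance was not excluded, and 0 of the 4850 genes passed.

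The replicate numbers of the labels did not pair the tumours, with correlations of −0.12 to 0.48 and only numbers 1 and 6 each matching best with their own number. The replicate block gave 0 genes and 0 lists, with 1667 genes at an unadjusted p under 0.05 and Ptk2 at 0.08.

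For 92 named genes besides Ptk2, 1251 of 1271 values under other settings and 1102 of 1104 with an array left out kept their sign and side of the threshold. Besides Osbp2 and Ret, Zfp422 and Stac passed without FAKi 1. For list shifts this held for 529 of 612 values and for 368 of 432 with an array left out, and 11 were camera's calls. The values that changed sign were small in most cases, none of them past the threshold. The cause was not tested unless it is given.

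Under quantile normalisation these were cytotoxic (−0.0025), STAT3 response (−0.034) and endocrine pancreas (−0.021). With normexp they were contractile (0.028), T cells (0.0068), ductal (0.028), endocrine pancreas (−0.0039), skeletal muscle (0.19) and r of matrix and cytotoxic scores (0.066), and with median centring STAT3 response (−0.020) and r of matrix and cytotoxic scores (0.12). In the authors' deposited table they were Btbd11 (0.31), cytotoxic (−0.012), STAT3 response (−0.033) and endocrine pancreas (−0.016). For Btbd11 the cause is the probe. That table holds both probes, and the second is the brighter there on 3 arrays' spots left out here as outliers, while the first gives −2.18. A filter on all 12 arrays turned inflammatory fibroblasts (0.024), ductal (0.077), endocrine pancreas (−0.33), skeletal muscle (0.18), mesothelium (−0.12) and r of matrix and cytotoxic scores (0.080), and fewer probes entered. The mean of a gene's probes turned Ptk2 (−0.12), H2-Ob (0.038), Myh2 (−0.45), focal adhesion (0.057), contractile (0.022), T cells (0.043), MHC class II (0.0097), ductal (0.0064) and MAPK output (0.012).

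Slide as a fixed block, and with the same values on the slides that hold both groups alone, turned Ptk2 (−0.13), Cald1 (−0.011), Mx1 (0.17), Ifit1 (0.25), Ido1 (0.27), Cfd (0.012), Tnni2 (−0.29), Myh2 (−0.012), matrix (0.11), T cells (0.54), monocytes (0.26), dendritic cells (0.066), MHC class II (0.43), type I interferon (0.39), cell cycle (−0.0044), ductal (0.23), mesenchymal transition (0.060), endocrine pancreas (−0.20) and gut epithelium (−0.14). Slide as a random block turned skeletal muscle (0.019). Leaving out the 3 arrays together turned Synpo2 (0.033), focal adhesion (0.066), matrix (0.33), contractile (0.23), inflammatory fibroblasts (0.025), T cells (0.049), macrophages (0.19), monocytes (0.051), MHC class II (0.043), STAT3 response (−0.0011), mesenchymal transition (0.17), skeletal muscle (0.63), gut epithelium (−0.32), immediate early genes (−0.0044) and r of matrix and cytotoxic scores (0.0047). A median list score turned matrix (0.034), contractile (0.022), ductal (0.082), MAPK output (0.0061), endocrine pancreas (−0.024) and skeletal muscle (0.15). Camera turned STAT3 response (−0.0035), endocrine pancreas (−0.081) and gut epithelium (−0.056) with either correlation, and fry skeletal muscle (0.19).

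With each array left out in turn, the range was fibroblasts −0.015 to 0.39, cytotoxic −0.19 to 0.26, STAT3 response −0.046 to 0.067, endocrine pancreas −0.051 to 0.27, skeletal muscle −0.96 to 0.37, ductal −0.32 to 0.14, T cells −0.24 to 0.18, gut epithelium −0.20 to 0.24, focal adhesion −0.090 to 0.039, matrix −0.13 to 0.12, contractile −0.31 to 0.14, macrophages −0.28 to 0.026, interferon-gamma −0.11 to 0.33, mesenchymal transition −0.25 to 0.082, MAPK output −0.11 to 0.041, r of matrix and cytotoxic scores −0.21 to 0.16, immediate early genes −0.0035 to 0.22, Ptk2 −0.0024 to 0.24, MHC class II −0.26 to 0.042, regulatory T cells −0.079 to 0.27, MHC class I −0.073 to 0.24 and monocytes −0.14 to 0.061. Shifts that kept their sign but moved by over 1.5 times with 1 array left out were inflammatory fibroblasts (−0.31 to −0.0096), B and plasma cells (−0.47 to −0.18), neutrophils (0.013 to 0.35), dendritic cells (−0.41 to −0.17), type I interferon (−0.33 to −0.022), cell cycle (0.15 to 0.36), endothelium (−0.56 to −0.21), adipocytes (−1.29 to −0.40), erythroid cells (−0.45 to −0.17), mesothelium (0.31 to 0.66) and hypoxia (−0.32 to −0.15). Signal over background limits dim genes such as Gzmf, Cfap45, Ret, Cldn3, Has2, Gzmb and Try4, whose probes were not well above background on all arrays.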

Other observations

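The relations in the next paragraph, their tests and the choice of granzyme genes came only after the result was seen.

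Tumours with high cytotoxic lymphocyte scores also had high interferon-gamma response scores, in 2 lists with no shared gene. Interferon-gamma is a cytokine that cytotoxic lymphocytes secrete, and its target genes include Cxcl10, Ido1 and Tap1. Over 12 tumours r was 0.92 (permutation p = 3e-05) and rho 0.90 (permutation p = 1.6e-04), with adjusted values of 2.1e-04 and 0.00112 over 7 relations. Without the 2 tumours farthest from the median r was 0.85, and with slide means taken away it was 0.92. Within FAKi tumours r was 0.96 (exact permutation p = 0.00139, n = 6) and within vehicle tumours 0.74 (exact permutation p = 0.0847, n = 6), and the difference between the groups was not tested. Both scores were highest in FAKi 5 (1.23 and 1.13) and lowest in FAKi 3 (−1.03 and −1.05), so FAKi tumours spanned the range. Of 5 other leukocyte lists, none shares a gene with the cytotoxic list. For macrophages no relation to cytotoxic scores was found over 12 tumours (r = 0.09, permutation p = 0.778, and rho = 0.25, permutation p = 0.428). For macrophages r was 0.09 without the 2 farthest tumours, 0.04 within vehicle, 0.17 within FAKi tumours and −0.13 with slide means taken away. Dendritic cell scores rose with cytotoxic scores (r = 0.78, permutation p = 0.00297, adjusted p = 0.0104, and rho = 0.78, permutation p = 0.00380, adjusted p = 0.0133). Neutrophil scores did so too (r = 0.74, permutation p = 0.00702, adjusted p = 0.0164, and rho = 0.71, permutation p = 0.0132, adjusted p = 0.0307). Without the 2 farthest tumours r was 0.63 and rho 0.68 for dendritic cells (permutation p = 0.0511 and 0.0352), and r was 0.57 and rho 0.55 for neutrophils (permutation p = 0.0849 and 0.104), so r no longer passed for either and, unadjusted, rho did for dendritic cells alone, while with slide means taken away r was 0.86 and 0.84. Monocytes (r = 0.20 and rho = 0.29, permutation p = 0.521 and 0.353) did not pass, nor did B and plasma cells after adjustment (r = 0.52 and rho = 0.63, permutation p = 0.0827 and 0.0327, adjusted p = 0.145 and 0.0573).

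That tumours with more cytotoxic lymphocyte transcripts hold more interferon-gamma response may be proposed as a hypothesis, but r over 12 tumours with group means taken away (0.92) is the relation first seen and does not test it. More leukocytes of every kind in a tissue piece was a candidate explanation, which would raise each leukocyte list alike. The correlation with cytotoxic scores was lower than that of interferon-gamma genes by 0.83 for macrophages (95% bootstrap 0.05 to 1.36, 99% −0.09 to 1.53), 0.72 for monocytes (0.21 to 1.23, 0.082 to 1.39), 0.40 for B and plasma cells (0.07 to 0.80, −0.02 to 0.997), 0.19 for neutrophils (−0.07 to 0.58, −0.16 to 0.86) and 0.14 for dendritic cells (−0.04 to 0.43, −0.12 to 0.58). Only the 99% interval of monocytes left out 0, and the correlation they are set against was followed up because it was high, which widens each difference, so more leukocytes of every kind stays open, and bulk values do not show which cells carried the response.

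Other granzyme genes beside Gzmf are given as values, chosen after these were seen and with no test of a difference between them. Gzmf gave 2.37 (adjusted p = 0.557) and Gzmg 2.34 (adjusted p = 0.853), while Gzmd gave −0.34, Gzme −0.69 and Gzmc −0.03, and none passed. Gzmg was well above background in 2 of 6 vehicle and 5 of 6 FAKi tumours. The sequences are near copies of each other, so a probe can read more than 1 of them.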
